A study of Mus musculus with 12 samples.

How the data were processed

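RNA was measured by sequencing in embryoid bodies, the aggregates that mouse embryonic stem cells form when they are left to differentiate in suspension. Per the labels, the stem cell lines came from embryos of an outbred strain that carried a floxed Trim33 allele on both chromosomes and a tamoxifen-dependent Cre recombinase, and were kept without feeder cells in LIF and 2i before differentiation. Loss of Trim33 was started with 4-hydroxytamoxifen on day 1, per the labels' protocols, and bodies were collected on day 2 and day 2.5. Whether the control cultures also received tamoxifen is not stated in the sources used here. The labels speak of 3 independent pairs but do not say that the replicate number marks the pair.

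The deposited files hold raw counts of reads per gene symbol, 1 file per library, and the authors made them with STAR and HTSeq on the mouse build mm9, per the submitters' processing notes, which also name DESeq. Tool versions, the annotation, the strand setting and the treatment of reads with several positions are not given in the sources used here. Genes with near-identical copies are therefore uncertain, as are genes that overlap another gene on the opposite strand, such as Xist and Tsix. The 5 closing rows of each file name no gene and were left out of library sizes and tests. Among all reads counted in the files, 55.9 to 60.5% fell in no annotated feature and 0.144 to 0.189% in more than one gene, and 39.3 to 43.9% were assigned to a gene. In 1 library, day 2.5 Trim33-deficient replicate 1, 27 gene names had been turned into dates by a spreadsheet, and they were restored by their position among the rows, which was the same in all files.

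Counts assigned to genes ranged from 10066338 to 16529627 per library. A count of 3, taken as the floor, equals 0.179 to 0.318 CPM, counts scaled to a common library size. These floors cover counting error only. Of 24015 gene rows, 19581 had any count and 14356 passed the edgeR filter on low counts and were tested. These CPM values were computed from the deposited counts with TMM-scaled library sizes.

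The main test was edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group, and a robust quasi-likelihood fit of 4 group means to all 12 libraries, with 8 residual degrees of freedom and no replicate block. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and a gene passed at an adjusted p under 0.05. Standard errors of log2 fold changes were obtained from the fold change and its F statistic. The 6 comparisons were Trim33-deficient against control on day 2, on day 2.5 and as the mean of both days, day 2.5 against day 2 in control and in Trim33-deficient bodies, and the interaction of genotype and day. Replicates are separate libraries per the labels. P-values measure the spread between these libraries, and nothing in the labels says how far the cultures behind them were separate beyond the mention of independent pairs.

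Gene lists, the tests and most alternatives were fixed before the data were examined. Of 30 lists, 27 were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. The lists overlap, so their results are not separate. Bambi and Smad7 are in both the Nodal/Activin and BMP target lists, and Tbx3 is in the naive and BMP lists. Cdx2, Gata3 and Hand1 are in the trophoblast and BMP lists. The TIF1 family and the sex-linked genes are described gene by gene, and mitochondrially encoded genes are not analysed here.

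The genes named were chosen by a rule fixed in advance: Trim33; per genotype comparison, the 10 largest rises and falls among genes past the threshold with a mean CPM of at least 1 and no overlap between the groups; up to 4 members of each list with the smallest adjusted p; smaller numbers for the other comparisons. For the interaction the largest differences each way past the threshold were taken, with no CPM minimum and no condition on overlap. The rule as a whole returned more genes than the text could hold. Those described were picked from it after their values and their stability under the alternatives had been seen, mostly among genes that kept their call, so the named genes look more stable than the full set. Some genes that the rule returned are not reported here. On day 2, 36 of the 69 genes returned kept their call under every alternative run on them, and on day 2.5 112 of 121. For the interaction 2 of 11 kept their result, but Trim33 is counted in both numbers. It did not pass the interaction test and so had no call to keep. DESeq2 gave an adjusted p for only 6 of these 11.

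Alternatives planned in advance were other size factors, other filters, DESeq2 1.42.0, fits on the compared libraries alone, replicate blocks and leaving out each library in turn. Fits without libraries that stood apart, and without ribosomal RNA rows, were added after seeing the data. The scripts were tested on simulated counts for 14356 genes, of which 200 were changed by known folds. For the day 2 comparison the main test recovered 54% of genes changed 1.5-fold and 78% of those changed 2-fold, and 3.94% of its calls were false. For the interaction it recovered 40% and 70%, with 8.93% false calls. Counts were drawn once per comparison, without correlation between genes and without libraries that stood apart. They also held fewer changed genes than any comparison called here, so these rates need not hold for the real data.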

Results

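The data are gene counts from 12 RNA libraries of mouse embryoid bodies in 4 groups of 3: control and Trim33-deficient, each on day 2 and day 2.5 of differentiation. The series set out to find genes that differ between control bodies and bodies that had lost Trim33, a chromatin-binding regulator in TGF-beta family signalling. Libraries held 10066338 to 16529627 counts assigned to genes. Some libraries stood apart from their groups. The ribosomal RNA precursor Rn45s took 7.87% of counts in day 2 Trim33-deficient replicate 1 and 11.9% in day 2.5 control replicate 2, against 0.609 to 1.67% in the others. On day 2.5 it was 1.08 to 1.67% in the Trim33-deficient libraries but 0.609 and 0.727% in control replicates 1 and 3, and 0.636 and 0.688% in day 2 Trim33-deficient replicates 2 and 3. A difference in RNA preparation that goes with genotype on day 2.5, or with time in Trim33-deficient bodies, is therefore not excluded. Genes of the hypoxia and glycolysis list lay 0.67 above the mean of all libraries on the log2 scale in day 2 control replicate 2 and 0.46 above it in day 2.5 control replicate 2. The other 10 lay between -0.30 and 0.03.

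Trim33 itself was low in every library labelled Trim33-deficient. On day 2 it stood at 271 ± 8.55 CPM in control bodies and 66.0 ± 4.88 CPM in Trim33-deficient bodies (SD, n = 3 each). On day 2.5 the levels were 250 ± 12.8 and 58.3 ± 4.23 CPM (SD, n = 3 each). The fall was 4.09-fold on day 2 (log2 fold change -2.03 ± 0.06 SE, adjusted p = 1.00e-11) and 4.28-fold on day 2.5 (-2.10 ± 0.06, adjusted p = 6.35e-12, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Its size did not differ detectably between the days (interaction -0.07 ± 0.09, adjusted p = 0.724). Of the relatives of Trim33, Trim24 stood at 0.10 ± 0.05 on the log2 scale on day 2 (adjusted p = 0.199) and rose by 0.14 ± 0.05 on day 2.5 (adjusted p = 0.0297), a call that some alternatives ended, while Trim28 and Trim66 did not pass on either day.

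**Figure D1:**
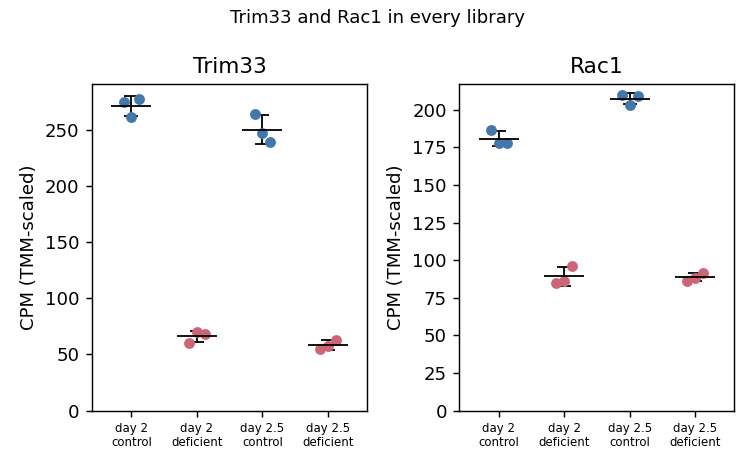
CPM of Trim33 and Rac1 in each of the 12 libraries, on linear axes from 0, by group; points are libraries, long bars group means and error bars SD (n = 3). Trim33-deficient libraries lie below all control libraries for both genes, with Trim33 means of 66.0 and 58.3 CPM against 271 and 250 CPM.

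The first comparison asked which genes differed 1 day after the induction of Trim33 loss, on day 2. Among the genes that rose, Fgfbp1, a carrier protein for fibroblast growth factors, rose 3.96-fold (log2 1.99 ± 0.15 SE, n = 3 each), and Ctgf, a secreted matrix protein, rose 2.98-fold from 35.5 ± 4.12 to 106 ± 18.0 CPM (SD). Socs3, a feedback inhibitor of the LIF and STAT3 pathway, rose 3.32-fold, and Stat3 2.04-fold (log2 1.03 ± 0.10). Among the genes that fell, Rac1, a small GTPase that controls the actin cytoskeleton, dropped from 181 ± 5.04 to 89.2 ± 6.13 CPM (log2 -1.02 ± 0.05, adjusted p = 1.14e-08), and Hopx, a small homeodomain protein, fell 2.08-fold (log2 -1.06 ± 0.21, adjusted p = 0.00591). Fgfbp1 had an adjusted p of 4.58e-06 and Ctgf of 1.39e-06 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. In all, 853 genes rose and 560 fell of 14356 tested, with 89 and 14 past 2-fold. With upper-quartile factors 784 rose and 730 fell, with RLE factors 835 and 578, and by DESeq2 865 and 637. The size of the excess of rises therefore depended on which scaling was used. This total of 1413 depended on single libraries: it was 569 without day 2 control replicate 3, and 527, 798 and 892 without day 2 Trim33-deficient replicates 1, 2 and 3. Leaving out both libraries rich in ribosomal RNA gave 814.

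Most genes of the cholesterol synthesis list rose on day 2. Of 22 measured members 19 rose, 0 fell and 3 did not pass, and adjusted over the list alone 21 rose. Cyp51, the lanosterol demethylase, rose from 169 ± 6.16 to 289 ± 6.48 CPM (SD, n = 3 each; log2 0.77 ± 0.05 SE), and Sqle, the squalene epoxidase, by 0.62 ± 0.05 on the log2 scale. Camera gave the list an adjusted p of 6.04e-37, and adjusted p = 0.0200 with an estimated correlation. Without day 2 control replicate 3 the number of members that rose was 12.

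More p53 targets rose than fell on day 2. Of 25 members of the p53 and DNA damage list 15 rose, 1 fell and 9 did not pass, and adjusted over the list alone 17 rose and 1 fell. Btg2, an antiproliferative gene, rose by 0.69 ± 0.09 on the log2 scale, Perp, a cell-junction and apoptosis gene, by 0.93 ± 0.14, and Phlda3 and Eda2r by 0.49 ± 0.08 and 0.48 ± 0.07 (SE). The adjusted p by camera was 2.52e-13, and adjusted p = 0.138 with an estimated correlation. The 1 member that fell, Rps27l (log2 -0.18 ± 0.05, chosen for mention after its values were seen), did not keep its call when any of 5 of the day 2 libraries was left out (all except control replicate 2).

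On day 2 more naive pluripotency genes rose than fell, and more primed ones fell than rose. Of 21 naive pluripotency genes 9 rose, 1 fell and 11 did not pass, and adjusted over the list alone 13 rose and 2 fell; the list had an adjusted p of 3.85e-11 by camera, and adjusted p = 0.138 with an estimated correlation. Esrrb and Tfcp2l1, transcription factors of the naive state, rose by 1.19 ± 0.14 and 1.15 ± 0.16 on the log2 scale (SE). Of 20 primed epiblast genes 1 rose, 7 fell and 12 did not pass, and adjusted over the list alone 2 rose and 8 fell (camera adjusted p = 0.00300, and adjusted p = 0.398 with an estimated correlation). Fgf15 and the DNA methyltransferase Dnmt3a fell by 0.70 and 0.44 on the log2 scale. The number that fell was 2 without control replicate 3 or Trim33-deficient replicate 1 of day 2, 4 without control replicate 2 or Trim33-deficient replicate 2, and 3 without all 3 libraries that stood apart. The 1 naive gene that fell, Nanog, is described for day 2.5, because its day 2 call was lost without several single libraries.

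Camera also called other lists on day 2. Of 25 cell cycle genes 8 fell, 0 rose and 17 did not pass, and adjusted over the list alone 9 fell and 1 rose (adjusted p = 0.00178 by camera, and adjusted p = 0.138 with an estimated correlation). The replication genes Mcm6 and Rrm2 fell by 0.26 and 0.28 on the log2 scale. The count that fell was 3 without day 2 control replicate 3 and 2, 4 and 5 without Trim33-deficient replicates 1, 2 and 3. Of 16 BMP target genes 3 rose, among them Bambi, a decoy receptor, by 0.69 ± 0.10, and 13 did not pass, with 4 that rose and 1 that fell adjusted over the list alone (camera adjusted p = 0.0202, and adjusted p = 0.138 with an estimated correlation; 1 rose without control replicate 3, where the camera adjusted p was 0.0576, or without Trim33-deficient replicate 1 or 2). Of 19 germline genes 1 rose, 3 fell and 15 did not pass, with 1 and 5 adjusted over the list alone (camera adjusted p = 0.00512, and adjusted p = 0.247 with an estimated correlation); Tdrd1, a piRNA pathway gene, fell by 0.61, and only 1 gene fell without control replicate 3 or Trim33-deficient replicate 2.

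The remaining lists on day 2 are given as counts. Interferon response genes gave 1 of 12 that rose, Ddx58, a cytoplasmic RNA sensor, by 0.94 ± 0.10 on the log2 scale, with 4 that rose and 1 that fell adjusted over the list alone (camera adjusted p = 0.0374, and adjusted p = 0.493 with an estimated correlation); the camera call ended without day 2 control replicate 1 (adjusted p = 0.247), control replicate 3 or Trim33-deficient replicate 2, and without all 3 libraries that stood apart 4 rose (camera adjusted p = 0.000607). Nodal/Activin targets gave 3 of 15 that rose and 0 that fell, also adjusted over the list alone, and 1 rose without any of the day 2 libraries other than control replicate 2; its median and mean were negative (-0.13 and -0.01) and the camera direction up, with no call (adjusted p = 0.789). Of 20 Nodal/TGF-beta pathway components 2 rose, of 13 definitive endoderm genes 1, of 10 hemangioblast and blood genes 1 rose and 1 fell, and of 14 neuroectoderm genes 2 fell. FGF/ERK response genes gave 3 of 19 that rose, and 1 without day 2 control replicate 2, day 2 Trim33-deficient replicate 1 or 2, or day 2.5 Trim33-deficient replicate 2. Of 22 integrated stress and early response genes 3 rose, and 1 without day 2 Trim33-deficient replicate 1. Trophoblast genes gave 2 of 13 that rose, with Tfap2c up by 1.33 ± 0.19. Of 17 primitive and visceral endoderm and 16 epithelial and mesenchymal genes 1 each rose, and of 16 Wnt targets and 11 fibroblast markers 1 each fell. Adjusted over the list alone, hemangioblast and blood genes gave 1 that rose and 3 that fell. Primitive and visceral endoderm gave 2 and 1, trophoblast 2 and 1, and FGF/ERK 3 and 1. Of 28 DNA methylation and imprinted genes 3 rose and 4 fell; 1 fell without day 2 control replicate 3, 2 without day 2 control replicate 1 or Trim33-deficient replicate 1 or 2, and 5 rose without day 2.5 control replicate 2. Without all 3 libraries that stood apart 8 fell, and camera passed the list (adjusted p = 0.0437).

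In 6 lists no member passed on day 2. By edgeR 0 members passed among 16 primitive streak, 17 two-cell-like, 13 general pluripotency, 12 precardiac, 13 histone and 25 hypoxia and glycolysis genes, where 1, 0, 2, 1, 0 and 3 had an unadjusted p under 0.05 and DESeq2 passed 1 hypoxia and glycolysis gene and 0 of the others. The hypoxia and glycolysis genes are those that lay 0.67 high in day 2 control replicate 2. These zeros depended on the libraries used: without all 3 that stood apart, 2 two-cell-like genes fell (camera adjusted p = 0.000396), 3 general pluripotency genes fell (0.0541), and 4 hypoxia and glycolysis genes rose and 1 fell (0.0204). Streak, precardiac and histone genes still gave 0, though camera passed the histone list (adjusted p = 0.0437).

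On day 2.5, where the same question was asked, more genes passed than on day 2. Lgals3, a galactose-binding lectin, rose 9.78-fold, from 1.64 ± 0.581 to 16.2 ± 2.10 CPM (SD, n = 3 each), and P2rx7, an ATP-gated ion channel, rose 8.72-fold, from 6.39 ± 0.624 to 56.2 ± 12.9 CPM. Fgfbp1 rose 8.26-fold (log2 3.05 ± 0.13 SE, adjusted p = 3.56e-09) and Sox8, a transcription factor, 8.15-fold (log2 3.03 ± 0.24, adjusted p = 2.73e-07, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Rac1 fell from 207 ± 3.67 to 88.6 ± 2.62 CPM (log2 -1.23, adjusted p = 4.44e-10). Dok5, an adaptor of receptor tyrosine kinases, fell by 1.93 ± 0.24 on the log2 scale and Camk1g, a calcium-dependent kinase, by 2.15 ± 0.34. In all, 3165 genes rose and 2978 fell, with 837 and 216 past 2-fold. With upper-quartile factors 2993 rose and 3293 fell, so which direction held more genes depended on the scaling. Leaving out the ribosomal rows gave 6125 genes, which does not remove other effects of RNA preparation.

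The day 2 and day 2.5 comparisons share no libraries, but they came from the same fit with a shared estimate of spread. Some control libraries of the same number also went together over the days (correlations 0.365 and 0.451). The comparisons are therefore not fully independent. Of the 1413 genes that passed on day 2, 1209 passed in the same direction on day 2.5, 738 higher and 471 lower, where independent lists would share 188 and 116, and 6 passed in the opposite direction. The log2 fold changes on both days had Pearson's r = 0.60 across genes, which are not independent replicates.

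Most naive pluripotency genes rose on day 2.5. Of 21 members 19 rose, 1 fell and 1 did not pass, also adjusted over the list alone (camera adjusted p = 4.45e-16, and adjusted p = 0.0934 with an estimated correlation). Esrrb rose 4.68-fold, from 28.0 ± 2.14 to 131 ± 21.0 CPM (SD, n = 3 each), Tfcp2l1 4.15-fold, Fbxo15 3.99-fold and Stat3 2.57-fold. The member that fell was Nanog, chosen for mention after its values were seen, from 182 ± 23.5 to 75.8 ± 6.54 CPM (log2 -1.26 ± 0.15, adjusted p = 7.60e-05). General pluripotency genes, 13 in all, gave 8 that rose, 1 that fell and 4 that did not pass, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.0599), although it was without all 3 libraries that stood apart (0.0371). Of 20 primed epiblast genes 10 fell, 6 rose and 4 did not pass, also adjusted over the list alone (camera adjusted p = 0.0370, and adjusted p = 0.483 with an estimated correlation), and the camera call ended without day 2.5 control replicate 1 (adjusted p = 0.153). Fgf15 and Zic2 fell by 1.07 and 0.84 on the log2 scale, and Grhl2, an epithelial transcription factor, rose by 0.53 ± 0.07. The number of primed genes that rose was 3 without day 2.5 control replicate 2 or Trim33-deficient replicate 3.

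**Figure D2:**
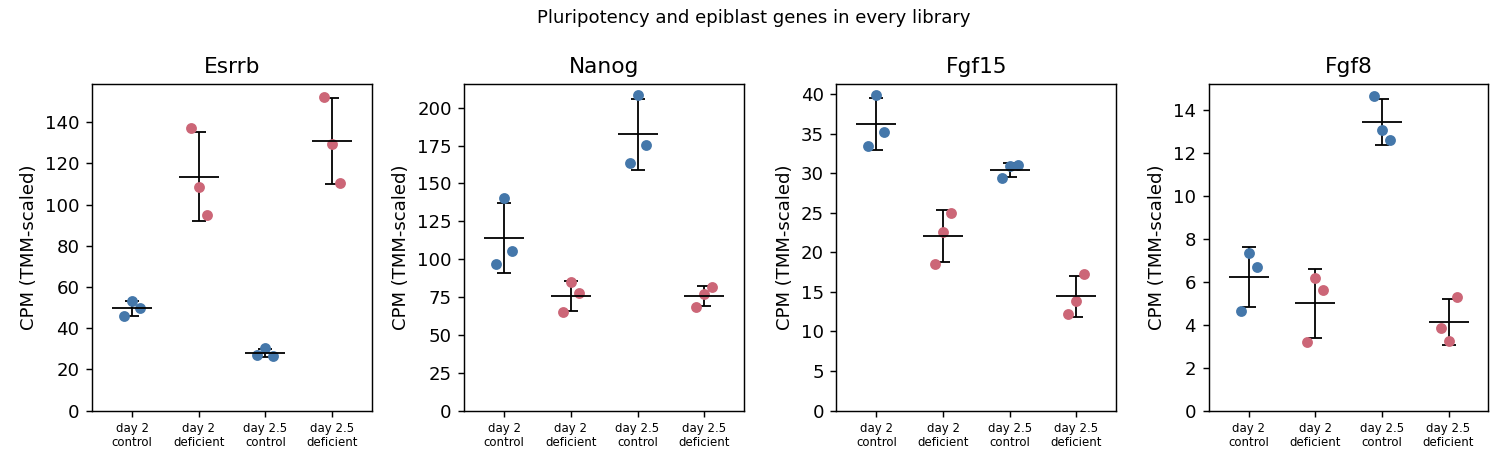
CPM of Esrrb, Nanog, Fgf15 and Fgf8 in each library by group on linear axes; points are libraries, long bars group means and error bars SD (n = 3). Esrrb averaged 131 CPM in Trim33-deficient and 28.0 CPM in control bodies on day 2.5, and Nanog 75.8 against 182 CPM.

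Signalling lists for the TGF-beta family held rises and falls on day 2.5, when 3165 of all 14356 tested genes rose and 2978 fell. Of 15 Nodal/Activin target genes 6 rose, 6 fell and 3 did not pass, the same adjusted over the list alone (not called, camera adjusted p = 0.828). Lefty1, a Nodal antagonist, rose by 0.94 ± 0.12 on the log2 scale and Skil, a SMAD co-repressor, by 0.30 ± 0.05, while Pmepa1, a SMAD inhibitor, fell by 0.72. Its median and mean were negative (-0.02 and -0.09) and the camera direction up. The 20 pathway components gave 3 that rose, 5 that fell and 12 that did not pass, also adjusted over the list alone (camera adjusted p = 0.510); 8 fell without day 2.5 control replicate 1 and 3 without control replicate 2 or 3 or Trim33-deficient replicate 1 or 2, and 1 rose without Trim33-deficient replicate 3. Of 16 BMP targets 9 rose, 2 fell and 5 did not pass, with 10 and 2 adjusted over the list alone (camera adjusted p = 0.00703, and adjusted p = 0.140 with an estimated correlation). Id1 and Id2, inhibitors of differentiation, rose by 0.99 ± 0.13 and 0.76 ± 0.10, and Tbx3 by 1.51 ± 0.26. Of 16 primitive streak genes 3 rose, 4 fell and 9 did not pass, also adjusted over the list alone (camera adjusted p = 0.828): Fgf8 and Eomes, expressed in the streak, fell by 1.69 ± 0.22 and 0.99 ± 0.16, while Nodal and Snai1 rose by 0.58 ± 0.09 and 1.23 ± 0.19. The median of the streak list was positive (0.09) and its mean negative (-0.09).

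The two-cell-like, trophoblast and germline lists held more rises than falls on day 2.5. Of 17 genes of the two-cell-like state, a rare cell state in stem cell cultures, 16 rose, 0 fell and 1 did not pass, the same adjusted over the list alone (camera adjusted p = 1.89e-09, and adjusted p = 0.321 with an estimated correlation). Zscan4f rose by 1.65 ± 0.23 on the log2 scale and Arg2 by 1.77 ± 0.20, from 5.77 ± 1.56 to 20.0 ± 2.58 CPM (SD, n = 3 each). Many genes of this list belong to multicopy families, and how reads shared between copies were counted is not stated, so the number of separate genes is uncertain. Of 13 trophoblast genes 6 rose, 2 fell and 5 did not pass, also adjusted over the list alone (camera adjusted p = 0.00816, and adjusted p = 0.321 with an estimated correlation), with Tfap2c, Ascl2 and the keratin Krt8 up by 2.11 ± 0.18, 1.80 ± 0.22 and 1.11 ± 0.12. Of 19 germline genes 8 rose, 1 fell and 10 did not pass, also adjusted over the list alone (camera adjusted p = 0.0301, and adjusted p = 0.348 with an estimated correlation), with Tex19.1 up by 1.99 ± 0.19 and Stk31 by 0.96 ± 0.09.

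Most cholesterol and p53 genes rose on day 2.5 as well. Of 22 cholesterol genes 20 rose, 0 fell and 2 did not pass, also adjusted over the list alone (camera adjusted p = 1.09e-20, and adjusted p = 0.0934 with an estimated correlation), and Cyp51 rose 2.28-fold (log2 1.19 ± 0.05 SE, n = 3 each). Of 25 p53 and DNA damage genes 21 rose, 1 fell and 3 did not pass, with 21 and 2 adjusted over the list alone (camera adjusted p = 9.92e-15, and adjusted p = 0.140 with an estimated correlation). Mdm2, the p53 ubiquitin ligase, rose by 1.26 ± 0.10 on the log2 scale, Eda2r by 1.00 ± 0.07 and Polk, a translesion polymerase, by 0.79 ± 0.07. Of 22 integrated stress and early response genes 14 rose, 1 fell and 7 did not pass, with 14 and 2 adjusted over the list alone (camera adjusted p = 0.00377, and adjusted p = 0.321 with an estimated correlation), with Atf3 up by 1.53 ± 0.25 and Phgdh, a serine synthesis enzyme, down by 0.55 ± 0.08. Of 25 cell cycle genes 15 fell, 4 rose and 6 did not pass, with 16 and 4 adjusted over the list alone (camera adjusted p = 0.0303, and adjusted p = 0.321 with an estimated correlation). Cdkn2b, a cell cycle inhibitor, was among those that rose, 2.83-fold, and Ccna2 fell by 0.33. Of 28 DNA methylation and imprinted genes 15 rose, 5 fell and 8 did not pass, with 15 and 6 adjusted over the list alone (camera adjusted p = 0.00703, and adjusted p = 0.483 with an estimated correlation), with Impact and Plagl1, both imprinted, up by 0.73 ± 0.06 and 1.35 ± 0.17. The number that fell was 2 without day 2.5 control replicate 1 and 1 without control replicate 3 or Trim33-deficient replicate 1.

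**Figure D3:**
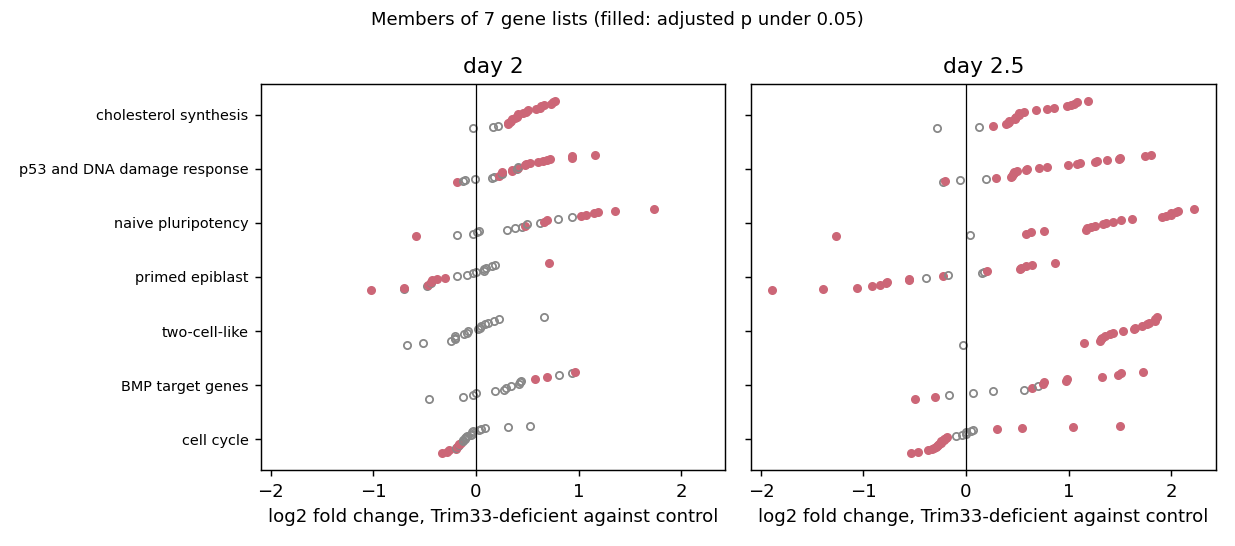
Log2 fold change of each tested member of 7 gene lists, Trim33-deficient against control, on day 2 (left) and day 2.5 (right); filled points had an adjusted p under 0.05. On day 2.5 20 of 22 cholesterol genes and 16 of 17 two-cell-like genes are filled on the right of 0, against 19 and 0 on day 2.

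The remaining lists were not called on day 2.5 with all libraries. Without the 3 that stood apart, camera passed the FGF/ERK (adjusted p = 0.0168) and interferon lists (0.0323, with 6 that rose and 1 that fell). Definitive endoderm gave 6 of 13 genes that rose and 3 that fell, precardiac mesoderm 4 of 12 that rose and 0 that fell, and hemangioblast and blood 2 of 10 each way. Neuroectoderm gave 5 of 14 each way, primitive and visceral endoderm 6 of 17 that rose and 3 that fell, and the epithelial and mesenchymal list 7 of 16 and 4. Wnt targets gave 4 of 16 each way and FGF/ERK response genes 11 of 19 that rose and 2 that fell (camera adjusted p = 0.0812). Interferon response genes gave 4 of 12 that rose and 2 that fell, with Ddx58, a cytoplasmic RNA sensor, up by 1.69 ± 0.11 on the log2 scale. Fibroblast markers, included as a check on another cell type, gave 3 of 11 that rose and 5 that fell, and replication-dependent histones 0 of 13 either way by edgeR, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. Medians and means of the neuroectoderm and Wnt lists were positive where the camera direction was down, and the median of the primitive and visceral endoderm list was negative (-0.03) where its mean was positive (0.25). Of 25 hypoxia and glycolysis genes 1 rose and 3 fell, where day 2.5 control replicate 2 lay 0.46 above the mean of all libraries; without it 3 rose and 1 fell, and without all 3 that stood apart 5 rose and 4 fell. Without day 2 control replicate 2 the counts were 2 and 5, and 1 fell without any of the day 2 Trim33-deficient libraries or day 2.5 Trim33-deficient replicate 1 or 2. Among day 2.5 libraries, 3 neuroectoderm genes fell without control replicate 2 or 3 or Trim33-deficient replicate 1 or 2, 2 precardiac genes rose without Trim33-deficient replicate 2, 2 interferon genes rose without control replicate 3 or Trim33-deficient replicate 1, and 1 fibroblast marker rose without control replicate 3 or Trim33-deficient replicate 1 or 2. Adjusted over the list alone, neuroectoderm gave 5 that rose and 6 that fell, FGF/ERK 11 and 3, and hypoxia and glycolysis 0 and 1.

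As the mean of both days, with 6 libraries against 6, 3188 genes rose and 3061 fell, but with upper-quartile factors 2950 rose and 3478 fell. Fgfbp1 rose by 2.52 ± 0.10 on the log2 scale (adjusted p = 9.45e-10), Smok4a, a testis kinase, by 2.42 ± 0.28 and Ahnak, a large membrane-associated protein, by 2.38 ± 0.23 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Fgfbp1 and Smok4a also passed the interaction test, so these means describe neither day. On day 2 and day 2.5 the log2 fold changes were 1.99 and 3.05 for Fgfbp1 and 1.17 and 3.66 for Smok4a. Cholesterol genes gave 21 of 22 that rose, also adjusted over the list alone (camera adjusted p = 7.76e-30, and adjusted p = 0.0363 with an estimated correlation).

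Over time in control bodies, 1177 genes were higher and 1136 lower on day 2.5 than on day 2. With RLE factors the counts were 1140 and 1166, and by DESeq2 1058 and 1144, so neither direction held more genes under every scaling. T, the brachyury transcription factor, rose by 1.42 ± 0.29 on the log2 scale, from 1.13 ± 0.263 to 3.08 ± 0.779 CPM (SD, n = 3 each), and Fgf8 by 1.11 ± 0.21. Of 16 primitive streak genes 3 rose and 13 did not pass, with 5 that rose adjusted over the list alone (camera adjusted p = 0.0230, and adjusted p = 0.307 with an estimated correlation), with 5 that rose without day 2.5 control replicate 2. Nr0b1, a nuclear receptor of the pluripotency network, and Fgf4 fell by 1.20 ± 0.18 and 0.53 ± 0.06. Of 21 naive pluripotency genes 2 rose, 7 fell and 12 did not pass, with 2 and 9 adjusted over the list alone (camera adjusted p = 0.000116, and adjusted p = 0.226 with an estimated correlation); 4 fell without control replicate 3 of either day. Of 22 cholesterol genes 10 fell and 12 did not pass, with 18 that fell adjusted over the list alone (camera adjusted p = 5.32e-10, and adjusted p = 0.175 with an estimated correlation). Of 19 germline genes 9 fell and 10 did not pass, with 11 that fell adjusted over the list alone (camera adjusted p = 1.29e-08, and adjusted p = 0.0825 with an estimated correlation), Hormad1 by 1.48 ± 0.20 and Fkbp6 by 0.91 ± 0.11. Of 22 integrated stress and early response genes 1 rose, 8 fell and 13 did not pass, with 2 and 10 adjusted over the list alone (camera adjusted p = 7.78e-05, and adjusted p = 0.175 with an estimated correlation), with Atf4 and Asns down by 0.46 ± 0.06 and 0.37 ± 0.06.

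The calls over time in control bodies varied with the libraries used, and of the 15 lists called by camera only some are described. Both lists included as checks were among them. Fibroblast markers gave 2 of 11 that rose and 1 that fell, also adjusted over the list alone (camera adjusted p = 0.0371, and adjusted p = 0.175 with an estimated correlation). Replication-dependent histones gave 0 of 13 either way with a median of 1.20 on the log2 scale (camera adjusted p = 0.0404, and adjusted p = 0.512 with an estimated correlation). The fibroblast call ended without day 2 control replicate 2 or 3 or day 2.5 control replicate 3 (adjusted p at most 0.0784). The histone call ended without day 2 control replicate 1 or 2 or day 2.5 control replicate 2 (at most 0.448). A difference in cell types or in RNA selection between the control libraries of the 2 days is therefore not excluded. The streak list's camera call ended without day 2 control replicate 2 or day 2.5 control replicate 1, where its adjusted p was at most 0.223. The two-cell-like list gave 4 of 17 that rose, with 12 adjusted over the list alone (camera adjusted p = 1.55e-05, and adjusted p = 0.307 with an estimated correlation), but 1 without day 2 control replicate 2 or 3 or day 2.5 control replicate 1, 11 without day 2 Trim33-deficient replicate 1 and 9 without day 2.5 control replicate 2. The total of 2313 changed genes was 1250 without day 2 control replicate 3, 1449 without day 2.5 control replicate 3, and 1378 in a fit of the compared libraries alone.

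Over time in Trim33-deficient bodies, 1305 genes were higher and 995 lower on day 2.5. Of 17 genes of the two-cell-like state 16 rose and 1 did not pass, the same adjusted over the list alone, Zfp352 by 3.09 ± 0.34 on the log2 scale, from 3.57 ± 1.78 to 28.4 ± 0.490 CPM (SD, n = 3 each), and Tdpoz3 by 3.28 ± 0.44 (camera adjusted p = 2.66e-42, and adjusted p = 0.0400 with an estimated correlation). Of 16 BMP targets 9 rose and 7 did not pass, with 10 that rose adjusted over the list alone, Id1 by 0.91 ± 0.13 and the homeobox gene Msx2 by 1.63 ± 0.27 (camera adjusted p = 1.62e-05, and adjusted p = 0.0400 with an estimated correlation). Of 25 p53 and DNA damage genes 14 rose, 1 fell and 10 did not pass, with 15 and 1 adjusted over the list alone (camera adjusted p = 2.69e-09, and adjusted p = 0.217 with an estimated correlation), and 9 rose without day 2 Trim33-deficient replicate 2. Of 20 primed epiblast genes 6 fell and 14 did not pass, with 1 that rose and 8 that fell adjusted over the list alone (camera adjusted p = 0.00185, and adjusted p = 0.232 with an estimated correlation), with Dnmt3a and Fgf15 down by 0.53 ± 0.07 and 0.62 ± 0.13. Of 21 naive pluripotency genes 6 rose, 1 fell and 14 did not pass, with 8 and 1 adjusted over the list alone (camera adjusted p = 0.00539, direction up, and adjusted p = 0.451 with an estimated correlation), the reverse of the direction in control. The number that rose was 2 to 10 with 1 library left out, and the camera call ended without day 2 Trim33-deficient replicate 3 (adjusted p = 0.0506). Of 22 cholesterol genes 1 rose, 5 fell and 16 did not pass, also adjusted over the list alone (camera adjusted p = 0.0161, and adjusted p = 0.499 with an estimated correlation), and 2 fell without day 2 Trim33-deficient replicate 3 or day 2.5 Trim33-deficient replicate 2. Camera called 13 lists in this comparison, and only some are described. Dppa3, a maternal-effect gene, rose by 1.28 ± 0.11 and Krt8 by 1.55 ± 0.12, while Rsad2, an antiviral gene, fell by 2.02 ± 0.36. T stood at 1.31 ± 0.290 CPM on day 2 and 1.06 ± 0.322 CPM on day 2.5 and did not pass. The total of 2300 changed genes was 1094 and 1311 without day 2 Trim33-deficient replicates 2 and 3, and 1218 and 1238 without day 2.5 Trim33-deficient replicates 1 and 2. It was 3699 without all 3 libraries that stood apart.

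The test of the difference between the days, the interaction of genotype and day, passed for 575 genes, 397 with a more positive and 178 with a more negative effect on day 2.5. Slfn2, an immune growth regulator, differed by 3.36 ± 0.86 on the log2 scale (adjusted p = 0.0413) and Lgals3 by 2.59 ± 0.36 (adjusted p = 0.00335). In the other direction T differed by -1.72 ± 0.43 (adjusted p = 0.0373) and Fgf8 by -1.41 ± 0.32 (adjusted p = 0.0252, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Of 17 two-cell-like genes 8 passed with a more positive effect on day 2.5, and 16 adjusted over the list alone (camera adjusted p = 4.47e-16, and adjusted p = 0.276 with an estimated correlation). This count of 575 rested on single libraries more than any other total here. It was 291, 1219 and 127 without day 2 control replicates 1, 2 and 3, 936, 138 and 131 without day 2 Trim33-deficient replicates 1, 2 and 3, 357 and 166 without day 2.5 control replicates 2 and 3, and 174 and 255 without day 2.5 Trim33-deficient replicates 1 and 2. Without both control libraries numbered 2 it was 1092, and without all 3 libraries that stood apart 1973. With a block for the replicate number shared over both days it was 1169. Of 38 described genes that passed, 8 did so with any 1 library left out, Lgals3 among them, and the calls of T, Fgf8 and Slfn2 were lost without 7, 6 and 8 of the 12 libraries.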

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

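Except for the day 2 test of the neighbours of Rac1, the tests in this part, or the limits they were judged by, were chosen or written down only after the result was seen, including the limits for counts over other splits of the libraries.

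These results are listed because the genotype effect differed between the days by the interaction test (day 2.5 effect minus day 2 effect, log2). Differences were positive for Fgfbp1 (1.06), Smok4a (2.49), Lgals3 (2.59), P2rx7 (1.79), Sox8 (1.92), Cyp51 (0.42), Eda2r (0.52), Mdm2 (0.65), Polk (0.38), Esrrb (1.04), Tfcp2l1 (0.90), Fbxo15 (1.30), Grhl2 (0.34), Snai1 (1.09), Cdkn2b (0.97), Krt8 (0.82), Ascl2 (1.37), Arg2 (1.54), Zscan4f (1.86), Stk31 (0.94), Tex19.1 (1.30), Rpl10l (0.76), Ddx58 (0.75), Slfn2 (3.36), Loxhd1 (3.01), Rapgef4 (2.93), Xist (1.00), Tsix (0.69), Dppa5a (0.79), Fkbp6 (0.72), Hormad1 (1.11) and Dppa3 (0.69). They were negative for Dok5 (-1.55), Mogat2 (-1.25), Fgf8 (-1.41), T (-1.72), Phgdh (-0.44) and Ano1 (-1.67). Xist and Tsix overlap on opposite strands and cannot be separated in these counts. Lists past the threshold by the camera interaction test with the preset correlation were naive pluripotency (adjusted p = 1.15e-10, 7 of 21 genes passed), general pluripotency (0.0133, 2 of 13), two-cell-like (4.47e-16, 8 of 17), germline (6.37e-10, 8 of 19), p53 and DNA damage (3.59e-07, 4 of 25), integrated stress (0.00373, 2 of 22, 1 in each direction), cholesterol (0.000726, 4 of 22) and DNA methylation and imprinted genes (6.46e-05, 3 of 28). Apart from the 1 integrated stress gene, all members that passed were more positive on day 2.5. None of these lists passed with an estimated correlation. The cholesterol call ended without the 3 libraries that stood apart (adjusted p = 0.249), without both rich in ribosomal RNA and without both control libraries numbered 2, and the general pluripotency call ended without day 2 control replicate 1 (adjusted p = 0.0787) or day 2.5 control replicate 2.

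Other splits of the same libraries bear on how far these counts can be trusted. For the interaction, 7 of 100 splits drawn gave at least the real 575 genes, the highest other giving 4020, several times the real count. All 6 others kept the real labels of day 2.5, so the genotype effect of that day enters their interaction, and the 93 drawn splits with other day 2.5 labels gave 0 genes at most. These splits therefore do not decide whether chance gave the 575 genes. For the mean of both days 1 of 100 splits, the real one, gave 6249 genes, against 3031 in the highest other. These splits exchanged labels within each day separately, as if the days held separate cultures. Control libraries numbered 1 and 2 went together over the days, so this share does not by itself exclude chance. With 3 libraries against 3 only 10 splits exist, too few for a share under 0.05: real and highest other counts were 1413 and 1 on day 2, 6143 and 0 on day 2.5, 2313 and 534 over time in control, and 2300 and 1 over time in Trim33-deficient bodies, each reached in 1 split.

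The number of lists called by camera with the preset correlation did not stand apart in the same way. For the mean of both days 28 of 100 splits gave at least the real 9 lists, the highest other 13. For the interaction 32 of 100 gave at least the real 8, the highest other 12. Groups of 3 cannot be mixed evenly, so every other split kept some of the genotype difference within each day. Camera weighs many genes together and can pick this up where no single gene passes. The splits therefore do not decide whether chance gave these lists, and chance is not excluded. Within a day or genotype the splits are too few: real and highest other counts were 8 and 12 on day 2 (6 of 10 splits), 11 and 13 on day 2.5 (3 of 10), 15 and 11 over time in control (1 of 10) and 13 and 11 over time in Trim33-deficient bodies (1 of 10). Because this stays undecided, a camera p with the preset correlation is not taken by itself to set a list apart here. It is printed as the value of that test beside the counts of members.

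The first pattern weighed is the low level of Rac1. Reads shared with a related gene might move counts to it, but Rac3, the only tested paralog, gained 1.86% ± 2.19 of the 91.5 CPM that Rac1 lost on day 2, far from the 50% set as the limit. Loss of a chromosome copy would lower its neighbours, but the 10 nearest tested genes had a median log2 fold change of 0.0318 ± 0.125 (SD over genes) on day 2, where 0 passed. On day 2.5 the median was 0.00442 ± 0.255 and 3 passed, 2 of them lower. That is a smaller share than among all genes, of which 6143 of 14356 passed. These 3 are thus no sign of a change particular to the region, though a change at single neighbours is not excluded. The day 2 neighbours argue against loss of a chromosome copy. How reads with several positions were counted is not stated, so shared reads need not appear at Rac3, and its small gain does not decide about them. An effect of Cre on the Rac1 locus itself, or of Trim33 loss, stays open and untested.

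The second pattern is the higher level of most cholesterol genes. Libraries that stood apart may have produced it, but 20 of 22 members rose on day 2 without the 3 such libraries. Exposure to tamoxifen or to active Cre could raise these genes without any role of Trim33, since the labels do not say whether any group was exposed without losing Trim33. The median interaction of the list, 0.16 on the log2 scale, does not decide this, and the effects of exposure and of Trim33 loss cannot be told apart here.

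The third pattern is the higher level of many p53 targets. Without the 3 libraries that stood apart, 13 of 25 members still rose on day 2, which argues against those libraries as the whole cause. DNA damage by active Cre is a candidate explanation that the design leaves open for the same reason. The median interaction of the list, 0.25, does not decide, and exposure and Trim33 loss cannot be told apart.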

How the results depend on the processing

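With upper-quartile factors the balance of directions turned: 2993 genes rose and 3293 fell on day 2.5, and 2950 and 3478 as the mean of both days. Over time in control bodies it turned with RLE factors (1140 higher, 1166 lower), by DESeq2 (1058 and 1144), without both libraries rich in ribosomal RNA and without some single libraries. Where a count moved the cause was not tested, except that fits with libraries left out hold fewer libraries. Genes changed on day 2 (1413) numbered 814 without both libraries rich in ribosomal RNA and 527 to 1618 with 1 library left out. Over time in control bodies (2313) there were 1378 in a fit of the compared libraries and 1250 to 2399 with 1 left out, and over time in Trim33-deficient bodies (2300) 3699 without all 3 libraries that stood apart and 1094 to 2733 with 1 left out. On day 2.5 the range was 4775 to 6522, and for the mean of both days 5395 to 6196. The interaction (575) gave 1092 without both control libraries numbered 2, 1973 without all 3 that stood apart, 848 without both rich in ribosomal RNA, 836 by DESeq2, and 127 to 1219 with 1 left out. By DESeq2 the other counts were 1502 on day 2, 5660 on day 2.5, 5794 for the mean, 2202 and 2169. Fits of the compared libraries alone gave 954 on day 2, 5930 on day 2.5 and 3301 over time in Trim33-deficient bodies.

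With a replicate block the interaction gave 1169 genes when the number was shared over both days and 712 with pairs within each day. Pairs as a block gave 1274 on day 2 and 5951 on day 2.5. With the number shared over both days there were 1870 on day 2 and 6541 on day 2.5. Over time that block gave 2776 in control and 2780 in Trim33-deficient bodies. No pairing of genotypes by number was detected. Between genotypes, libraries of the same number had correlations of deviations from their group means of 0.0745, 0.172 and -0.0788 on day 2. On day 2.5 these were -0.00944, -0.0330 and -0.0133. The highest other correlations were 0.113 on day 2 and 0.0246 on day 2.5, and not every library correlated best with its own number. Weak correlations in so few libraries cannot show that the numbers do not mark pairs. Between the days the correlations for the same number were 0.365, 0.451 and 0.0320 in control (highest other 0.175). In Trim33-deficient libraries they were 0.182, -0.0181 and 0.0878 (highest other 0.144). Control libraries numbered 1 and 2 thus went together over the days and those numbered 3 did not.

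Lists called numbered 8 on day 2 by camera, 1 with an estimated correlation and 21 by mixed fry. On day 2.5 they were 11, with 0 by estimated correlation, 19 by fry in 1 direction and 25 by mixed fry. For the mean of both days they were 9, with 1, 19 and 25. Over time in control bodies they were 15, with 0 by estimated correlation, 26 by mixed fry and 9 to 15 with 1 library left out. Over time in Trim33-deficient bodies they were 13, with 2 by estimated correlation and 26 by mixed fry. For the interaction they were 8, with 0 by estimated correlation, 2 by fry in 1 direction and 22 by mixed fry.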

Other observations

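The test in the last paragraph here was chosen after related overlaps between the time courses had been seen.

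Xist and Tsix, which overlap on opposite strands of the X inactivation centre, moved with genotype on day 2.5. Counts of Xist averaged 7.83 ± 1.20 CPM in control and 15.6 ± 1.39 CPM in Trim33-deficient bodies (SD, n = 3 each; log2 1.01 ± 0.13, adjusted p = 2.43e-05, edgeR), and Tsix rose by 1.08 ± 0.12. On day 2 Xist stood at 12.5 CPM in both groups, while Tsix had a log2 fold change of 0.39. From day 2 to day 2.5 the log2 fold change of Xist was -0.69 in control and 0.31 in Trim33-deficient bodies. Y-linked genes had at most 1 count in any library over 7 genes together, so all libraries look alike in this respect.

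The idea that Trim33-deficient bodies follow the control course less far was weighed on genes that changed over time, and the test does not decide it. Among genes that changed in control bodies, the median ratio of the Trim33-deficient to the control change was 0.386, and the mirrored ratio, among genes that changed in Trim33-deficient bodies, was 0.395. The difference of -0.00942 stayed between -0.0468 and 0.0451 with 1 library left out. Genes that change only in Trim33-deficient bodies lower the mirrored ratio too, so equal ratios cannot show that the control course was followed as far. Some values went opposite ways in control and Trim33-deficient bodies: medians of -0.62 and 0.15 for the germline list and -0.48 and 0.27 for the naive list, and 1.42 and -0.30 for T, which passed in control only.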
